A study of Mus musculus with 12 samples.

How the data were processed

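RNA from polysome gradients of 6 mouse livers was measured by RNA sequencing, with a heavy and a light pool per animal and 12 libraries in all. Per the labels' protocols, gradient fractions were combined into 2 pools per liver, the same amount of ERCC spike-in RNA was added to each pool, and 10 ng of RNA entered a stranded total RNA kit made for low inputs. Such a kit keeps ribosomal, mitochondrial and nuclear RNA along with mRNA unless they are depleted. The labels name each library heavy or light, and they do not say which range of fractions is which. The labels give a time of 0 h, while the protocol gives 24 h on the diet, so the time label was not used.

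The deposited values are raw counts per Entrez gene ID, 1 table per library, and they were used as deposited. Per the submitters' processing notes, Trimmomatic, HISAT2 and StringTie were used with mouse build mm10. Per the file headers, the counts of chow 1 and chow 2 came from Bowtie2 alignments and those of chow 3 and the S209A animal from HISAT2 alignments, while the headers of keto 1 and keto 2 name a read file and no aligner. Versions, the counting tool, its strand setting, its treatment of reads that align to several places and the annotation are not given in the sources used here. The sample titles follow the same line: they call chow 1, chow 2 and both keto animals chow or keto, and they call chow 3 and S209A fed. Antisense and overlapping genes, recent gene copies and processed pseudogenes are therefore uncertain, above all the Mup, Cyp2a, hemoglobin and 5S rRNA copies, Eno1b and Rpl37rt.

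The tables held 27179 IDs, and 25275 of them matched the RefSeq gene table of assembly GRCm38.p6 used here for symbols and chromosomes. The other 1904 stayed unnamed, including ID 100861531, the most counted ID over all libraries, which entered the fits under its number. The tables held 0 ERCC IDs, so the planned spike-in scaling was not run, and the planned pseudocounts did not apply to counts. No column was left unused (0).

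Genes were kept by edgeR's filterByExpr at a minimum of 10 counts, which left 10555. Libraries were scaled by TMM, whose factors ran from 0.324 to 3.12, since RNA other than mRNA took very different shares of the libraries. CPM, computed here from the deposited counts, is relative to the TMM-scaled library size. Every comparison used edgeR's quasi-likelihood test, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Heavy was set against light in 1 model over all 12 libraries with the animal as a block and a pool effect per condition, and differences in heavy over light between conditions were contrasts of that model. Keto and S209A were set against chow within each pool over its 6 libraries. The error after a log2 value is a standard error, taken as the absolute log2 change over the square root of edgeR's F statistic, unless SD is written. The heavy and light pool of 1 animal belong together by their labels, and deviations from the chow means were correlated within animals 1, 2 and 3 at r = 0.411, 0.361 and 0.313 across genes. Animals are the replicates. The single S209A animal has no replicate check, and its tests assume that it varies as the others do.

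In total 36 gene lists fixed before the data were examined covered fasting and feeding metabolism, translation, eIF4E, RNA quality and liver cell types. The metabolic lists were ketogenesis, mitochondrial β-oxidation, peroxisomal and ω-oxidation, other PPARα targets, lipogenesis, cholesterol synthesis, gluconeogenesis, glycolysis and fructolysis, bile acid synthesis and transport, amino acid catabolism and secreted plasma proteins. The translation lists were translation factors with a 5′ terminal oligopyrimidine motif, uORF-bearing stress response genes, ER chaperones, the eIF4E pathway, published phospho-eIF4E-sensitive mRNAs, cytosolic and mitochondrial ribosomal proteins and nuclear-encoded respiratory chain subunits. The quality lists were nuclear or untranslated RNA, mitochondrially encoded RNA, replication-dependent histones, immediate early genes, clock genes and the acute phase. The cell type lists were pericentral and periportal hepatocytes, Kupffer cells, sinusoidal endothelium, stellate cells, cholangiocytes, erythroid cells, lymphocytes, neutrophils, exocrine pancreas and adipocytes. The 32 lists with at least 5 measured members were tested with limma's camera at a preset inter-gene correlation of 0.01 and again with the correlation estimated, adjusted over the lists of a comparison. For S209A, a list's median was placed among 10000 random lists of equal size and matched expression, as a percentile and not a test.

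Genes were named by a rule in 3 parts. The first part took 10 genes per direction (5 for the light pool and for S209A) with the largest change among those that passed, at or above median expression and with 1 direction in every animal, filled up by the smallest unadjusted p and then said not to have passed. Predicted genes and pseudogenes were skipped. The second part named 16 genes, and the third took up to 4 members of a list, those with the smallest p. Not every gene that the rule picked is printed. Where every library of a group held 3 counts or fewer, counts are given in place of a fold.

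The alternatives were DESeq2, no expression filter, a mean of at least 50 counts, limma-voom, leaving out mitochondrial, ribosomal and small RNA genes, dropping the animal block, the title wording as a batch, the replicate number as a block across diets, and leaving out each animal. Ribosomal here means genes annotated as rRNA, so ribosomal protein genes and the most counted ID, which has no annotation here, stayed in. Keeping only nuclear protein-coding genes, the header wording as a random block in limma-voom, and the S209A pool labels exchanged, were added after seeing the data. The model was tested on counts simulated from the real means with 200 changed genes. Each gene had the same mean in all animals apart from these changes, and the spread left after the animal block. Differences between animals were therefore missing. The shares called within a pool, where animals are compared, can thus be too high, and the false calls too few. Of 8-fold changes above median expression it called 89.7% for heavy against light in chow (10555 genes), 86.8% for keto against chow in the heavy pool (10554 genes), 78.1% in the light pool and 53.6% for the keto difference in heavy over light (10555 genes each). Of 4-fold changes above median expression it called 51.7%, 40.5%, 35.7% and 0%, with 0, 4, 2 and 0 false calls. For S209A it called 43.6%, 51.5% and 22.2% of the 8-fold changes in the heavy pool, the light pool and heavy over light. In lists of 25 genes shifted 2-fold, camera called 20, 20, 20 and 19 of 20 lists for the 4 wild-type comparisons, and 0, 1, 0 and 0 of 20 unshifted ones. The simulated genes varied independently, while the real nuclear RNA list had an estimated correlation of 0.625 for heavy against light in chow. The simulation therefore cannot check the list calls made with the preset correlation. The analysis used Python 3.11.15, R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and matplotlib 3.10.9. Counting errors of the library shares below, as 95% Wilson intervals, were at most 0.0534 percentage points either way and cover counting error only. Fasted livers, which the series' design text mentions, were not analysed here.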

Results

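The series measured RNA in pooled sucrose gradient fractions from livers of male C57BL/6 mice, to compare RNA in heavy polysomes, which carry many ribosomes per mRNA, with RNA in light polysomes. Wild-type mice ate chow (3 animals) or a ketogenic diet, which is high in fat and poor in carbohydrate, for 24 h (2 animals). A chow-fed mouse carried the S209A change on both eIF4E alleles (1 animal). eIF4E binds the mRNA cap, and the serine that this change replaces is the site that the MNK kinases phosphorylate. Each animal gave a heavy and a light library. Library totals ran from 3341046 counts (S209A light) to 13263355 (keto 1 heavy).

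Most counts did not come from nuclear mRNA. Nuclear protein-coding genes held 15.9% and 22.2% of the counts in the heavy libraries of chow 1 and chow 2, and 29.7% in that of chow 3. They held 5.60% and 6.01% in the heavy libraries of keto 1 and keto 2, and 29.6% in that of S209A. In the light libraries the shares were 6.53%, 8.16% and 39.2% for chow 1, 2 and 3, 6.61% and 4.09% for keto 1 and 2, and 38.0% for S209A. The mitochondrial rRNAs held 12.1% (S209A light) to 74.2% (keto 2 heavy), and 1 ID without a name here held 15.9% to 59.1%. In heavy and light the mitochondrial rRNAs held 16.7% and 58.2% in chow 1, and 12.9% and 52.6% in chow 2. The order was the other way in keto 1 (47.3% and 37.6%) and keto 2 (74.2% and 51.8%), with chow 3 at 13.8% and 13.5%. The unnamed ID held 59.1% and 30.2% in chow 1 and 57.0% and 32.6% in chow 2, but 42.9% and 50.4% in keto 1 and 15.9% and 39.9% in keto 2. The depth that bears on mRNA was therefore 356544 counts in the shallowest library (keto 2 light) and 1776829 in the deepest (chow 3 heavy). Counts of genes annotated as pseudogenes, as a percent of protein-coding counts, were 0.535 to 0.941 in chow 1 and 2, 0.462 to 0.604 in keto and 0.0534 to 0.0669 in chow 3 and S209A. Per the headers, chow 3 and S209A share an aligner that differs from that of chow 1 and 2.

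**Figure D1:**
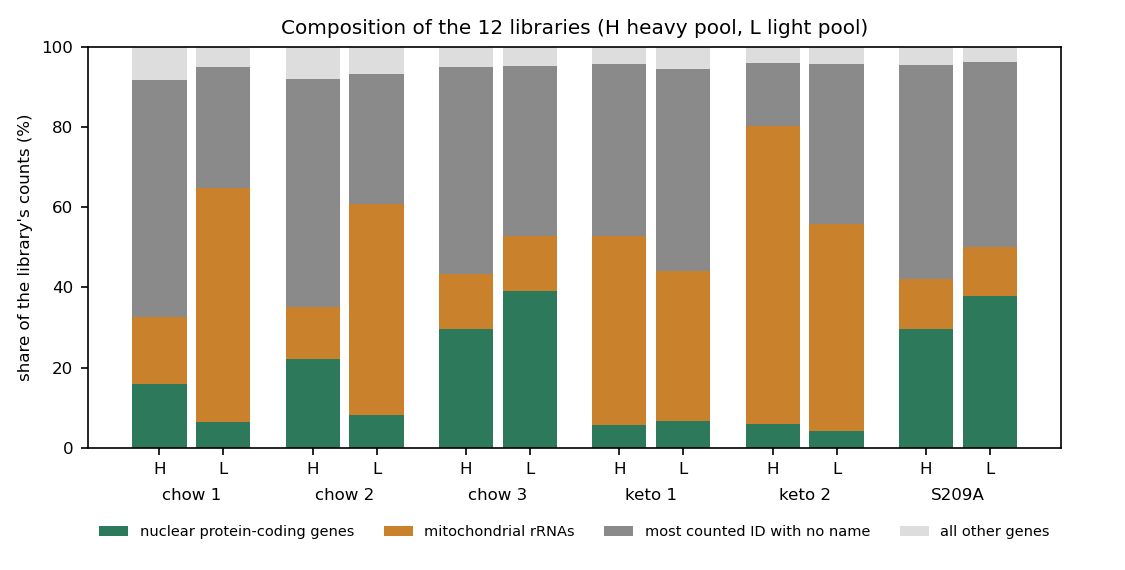
Share of each library's counts (percent, vertical axis) in nuclear protein-coding genes, the mitochondrial rRNAs, the most counted ID without a name and all other genes, for the heavy (H) and light (L) pool of each animal. Protein-coding shares were 29.6% to 39.2% in chow 3 and S209A and 4.09% to 22.2% in the other animals.

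In chow-fed livers the heavy pool held more mRNA of secreted, acute phase and pericentral hepatocyte genes than the light pool, and less nuclear RNA, by list medians that camera called with its preset correlation and not with an estimated one (lowest adjusted p = 0.407). Saa1, an acute phase apolipoprotein (chromosome 7, 46740497 to 46743181 in GRCm38.p6), was higher in heavy by log2 2.88 ± 0.42 (n = 3 animals, edgeR adjusted p = 1.09e-07). Its level was 54.3 ± 74.0 CPM (SD) in heavy and 7.86 ± 11.1 in light, so the animals differed widely while the ratio kept its sign in each. Fgb, the fibrinogen beta chain, was higher by 1.76 ± 0.41 (edgeR adjusted p = 0.0202), and the coumarin hydroxylase Cyp2a5 by 1.73 ± 0.37 (edgeR adjusted p = 0.00495). Rn7sk, the nuclear 7SK RNA that holds back transcription elongation, was lower in heavy by log2 -2.05 ± 0.44 (edgeR adjusted p = 0.00495).

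edgeR called 24 of 10555 genes, 17 higher and 7 lower in heavy, and called 0 at a mean of at least 50 counts or without the animal as a block (355 and 371 at an unadjusted p under 0.05). Among the higher ones were also Cyp2a4 (3.35), the mitochondrial aldehyde dehydrogenase Aldh1b1 (2.20), the histone gene H2ac18 (2.14), Eno1b (1.69), Rpl37rt (1.66), Lrg1 (1.49) and Fgl1 (1.44), with edgeR adjusted p of 0.000569 to 0.0463. Lcn2, a siderophore-binding acute phase protein, was called too, with 15, 8 and 170 counts in heavy and 2, 0 and 0 in light. Lower in heavy were Pfkfb3, a regulator of glycolysis (-3.25, with 0, 0 and 52 counts in heavy), the imprinted noncoding RNA Kcnq1ot1 (-2.24) and the organic anion transporter Slco1a1 (-1.63), with edgeR adjusted p of 0.0463 to 0.0493. Mapk3, which encodes ERK1, was called at -1.82, with its direction mixed across the animals. Sema6a (-2.58), Slmap (-1.72) and the RNA subunits of the RNase MRP and RNase P complexes, Rmrp (-1.34) and Rpph1 (-1.69), did not pass (edgeR adjusted p of 0.101 to 0.106).

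By gene list, 35 of 36 secreted plasma protein genes had a positive log2 value (median 0.64, camera adjusted p = 3.77e-14), with 1 passing over all genes and 2 adjusted over the list alone. Apoh, which binds phospholipids, stood at 1.20 and the plasma protein Itih4 at 1.06, and neither passed. In the acute phase list 14 of 17 were positive (median 0.96), with 3 passing, or 7 adjusted over the list alone. The iron hormone Hamp stood at 1.69 (edgeR adjusted p = 0.0751). Pericentral hepatocyte genes were positive in 16 of 17 (median 0.88), with 1 passing, or 6 adjusted over the list alone, and glutamine synthetase Glul stood at 1.02. Amino acid catabolism was positive in 23 of 27 (median 0.66), with 0 passing over all genes and 5 adjusted over the list alone, among them the ornithine aminotransferase Oat at 1.41. Replication-dependent histones, whose mRNAs lack a poly(A) tail, were positive in 22 of 27 (median 1.09), with 1 passing, or 5 adjusted over the list alone. All 12 nuclear or untranslated RNAs were negative (median -1.18, camera adjusted p = 2.43e-07), with 2 passing, or 5 adjusted over the list alone, and 14 of 15 mitochondrially encoded RNAs were negative (median -0.38). None of these list calls held with an estimated correlation (lowest camera adjusted p = 0.407 with an estimated correlation).

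Smaller positive medians were called by camera for cytosolic ribosomal proteins (0.59, 66 of 81 positive), glycolysis and fructolysis (0.63), cholesterol synthesis (0.61), mitochondrial β-oxidation (0.56), gluconeogenesis (0.56), ketogenesis (0.45), other PPARα targets (0.43), translation factors with a terminal oligopyrimidine motif (0.43), nuclear-encoded respiratory chain subunits (0.38), periportal hepatocytes (0.37), ER chaperones (0.36), peroxisomal and ω-oxidation (0.32), immediate early genes (0.28) and bile acid genes (0.23). Sinusoidal endothelial markers were negative in 12 of 16 (median -0.57). Adjusted over the list alone, 4 peroxisomal, 2 glycolysis, 2 PPARα target, 1 periportal and 2 bile acid genes passed, against 0, 0, 0, 1 and 1 over all genes, and 0 in the other 10 lists. The bile acid median turned to -0.0864 without chow 1 and -0.0386 at a mean of at least 50 counts, and that of PPARα targets to -0.0534 without chow 2. In camera these 15 lists had adjusted p of 3.82e-06 to 0.0477, and none passed with an estimated correlation (adjusted p of 0.407 to 0.587). Camera did not call Kupffer cells (0.17), mitochondrial ribosomal proteins (0.11), lipogenesis (0.17), cholangiocytes (0.19), erythroid cells (-0.62), published phospho-eIF4E-sensitive mRNAs (0.08), the eIF4E pathway (-0.17), clock genes (-0.18), uORF-bearing stress genes (-0.13) or stellate cells, whose median of -0.02 and mean of 0.46 differ in sign. The lymphocyte, exocrine pancreas and adipocyte lists had 1, 1 and 2 measured members and the neutrophil list 0, too few to test. Of the 16 genes fixed by name 0 passed in edgeR, with values from -1.41 (Mknk1, an eIF4E kinase) to 1.25 (Cyp4a14, a fatty acid ω-hydroxylase).

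The contrast was uneven across the chow animals. The secreted list's median heavy over light, relative to all genes, was 1.25, 0.77 and 0.16 in chow 1, 2 and 3, and that of nuclear RNA was -2.43, -1.81 and -0.12. The acute phase lay at 1.39, 0.83 and 0.73, pericentral genes at 1.35, 0.92 and 0.63, and ribosomal proteins at 0.36, 0.19 and 0.86, highest in chow 3. Lists that turned in chow 3 included histones (1.57, 2.28 and -0.21), mitochondrially encoded RNA (-0.59, -0.81 and 0.16), bile acid genes (0.95, 0.59 and -0.43), immediate early genes (0.54, 0.74 and -0.23) and PPARα targets (0.37, 0.77 and -0.19). Saa1 stood at 2.74, 2.48 and 2.94, and Cyp2a4, at 3.68, 0.69 and 4.55, was also highest in chow 3. Without chow 3, edgeR called 402 genes, and without chow 1, chow 2, keto 1 or keto 2 it called 5, 4, 8 and 11. DESeq2 called 127, of which 110 were higher and 17 lower.

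**Figure D2:**
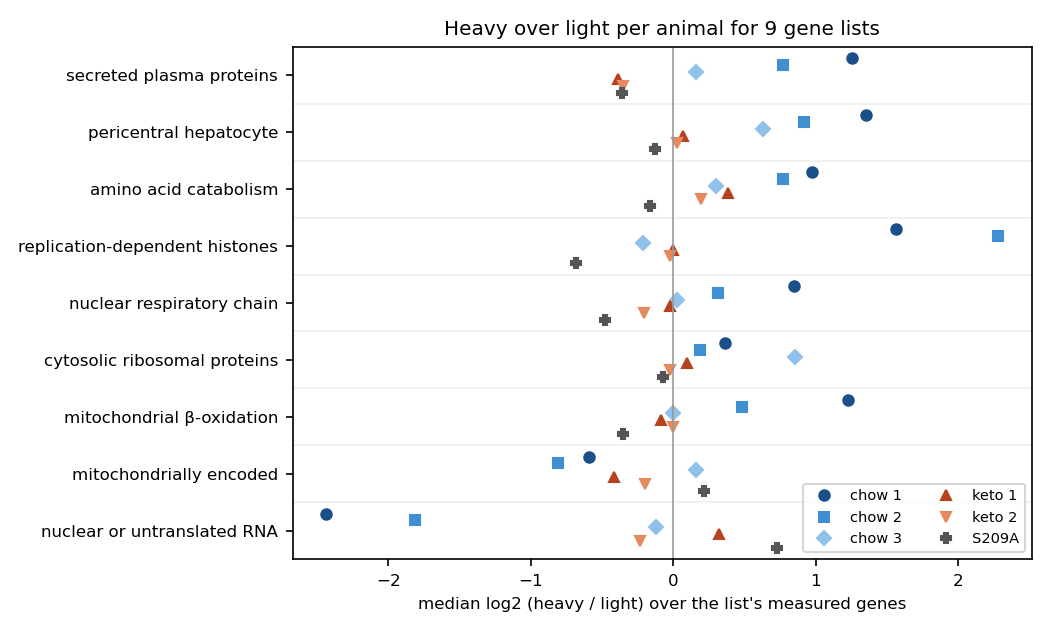
Median log2 heavy over light of 9 gene lists in each animal, relative to the median of all genes (horizontal axis), with 1 symbol per animal. Secreted plasma protein genes lay at 1.25 and 0.77 in chow 1 and 2, at 0.16 in chow 3, and at -0.39 and -0.36 in keto 1 and 2.

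In the heavy pool, secreted protein and acute phase mRNAs lay lower in the ketogenic diet animals than in chow, and nuclear and mitochondrial RNAs lay higher, by camera calls with the preset correlation that an estimated one did not bear out (adjusted p of 0.208 to 0.604). Hamp, the iron-regulating hormone hepcidin, was at 22.1 ± 4.52 CPM (SD, n = 2) against 322 ± 236 (n = 3), log2 -3.86 ± 0.77, and did not pass in edgeR over all animals (adjusted p = 0.228). Fgb stood at -2.82 ± 0.76 and Apom, an apolipoprotein of HDL, at -2.16 ± 0.51 (edgeR adjusted p of 0.476 and 0.407). Rn7sk stood at 3.85 ± 0.66 and Rpph1 at 4.11 ± 0.78 (edgeR adjusted p of 0.122 and 0.197).

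edgeR called 0 of 10552 genes in the heavy pool, with 862 at an unadjusted p under 0.05 (318 higher, 544 lower), while DESeq2 called 383 (116 higher, 267 lower) and limma-voom 4 (4 higher, with 516 higher and 404 lower at an unadjusted p under 0.05, the opposite balance). With the title wording as a batch, which sets keto 1 and 2 against chow 1 and 2, edgeR called 126 (31 higher, 95 lower), and without chow 3 it called 108. The header wording still parts these animals (a read file in keto, Bowtie2 in chow). The headers of chow 3 name HISAT2, so no chow library shares the keto wording. Diet and processing therefore cannot be told apart in any keto comparison, with or without that batch. In that batch fit the lower genes included Hamp (-4.14), Fgb (-3.09), Otc of the urea cycle (-2.73), Apoh (-2.38), Apom (-2.29), the chaperonin Hspd1 (-2.14) and the fatty acid synthase Fasn (-2.18), with edgeR adjusted p of 2.17e-04 to 0.0431. Pigk of the GPI transamidase (3.77), Rpph1 (3.86), Rn7sk (3.59), Dhdh (3.22) and Saa4 (2.72) were higher in it, with edgeR adjusted p of 2.17e-04 to 0.00812. Over all animals the other genes with the smallest p were Pigk (4.19), Dhdh (3.38), Pstpip2 (3.14), Cyb5r3 (2.86), Saa4 (2.82), Slc35e2 (2.80) and Fyco1 (2.16) on the higher side. On the lower side they were Rrp12 (-3.77), Bcap31 (-3.55), Hnrnph2 (-3.50), Ik (-3.11), Mphosph8 (-2.76), St13 (-2.21) and Hspd1 (-2.21). None of these passed over all animals (edgeR adjusted p of 0.118 to 0.407). Selenok held 2 and 2 counts in keto heavy and 11, 30 and 365 in chow, and the spliceosomal Rnu1b1 50 and 77 against 0, 2 and 0.

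Camera called 17 of 32 lists in the heavy pool, and 13 of them were also called in the same direction with the title batch. All 15 mitochondrially encoded RNAs were positive (median 1.78, camera adjusted p = 3.28e-12, 1.29 with the batch), as with ND1 at 2.28, ND4 at 1.83 and COX1 at 1.78. COX2, COX3, ATP6, ATP8 and ND4L held 0 to 3 counts in each library of chow 3 and S209A, while COX3 held 89 to 650 in the other animals, so part of this list is near absent from those files. Nuclear RNAs were positive in 11 of 12 (median 2.05, 2.40 with the batch), with 0 passing over all genes and 6 adjusted over the list alone (camera adjusted p = 0.208 with an estimated correlation). Kcnq1ot1 stood at 3.15 and Neat1, the scaffold of paraspeckles, at 2.07. Secreted protein genes were negative in 35 of 36 (median -0.99, -1.17 with the batch), acute phase genes in 14 of 17 (-1.15, -1.33 with the batch, 3 adjusted over the list alone), amino acid catabolism in 24 of 27 (-0.92, -1.02), periportal genes in 16 of 18 (-1.08, -1.20) and ER chaperones in 14 of 17 (-1.01, -1.06). Members that did not pass over all animals were Otc (-2.35), Apoh (-2.15), Tdo2 (-2.07), Pdia6 (-2.04), Ttr (-1.87) and Calr (-1.84). Histones were at -1.72 (-2.15 with the batch), cholesterol synthesis at -0.69 (-0.92, but 0.0479 without chow 1), glycolysis at -0.98 (-0.71), respiratory chain subunits at -0.81 (-0.40), pericentral genes at -0.45 (-0.79) and stellate markers at -0.52 (-0.65). Apart from nuclear RNA, these calls had camera adjusted p of 0.526 or 0.604 with an estimated correlation.

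Called lists that the batch fit did not call were cytosolic ribosomal proteins (-1.71, then -0.24, camera adjusted p = 0.387), oligopyrimidine translation factors (-1.08, then -0.05, camera adjusted p = 0.593, and 0.0602 with the replicate number as a block across diets), mitochondrial β-oxidation (-0.45, then -0.39, camera adjusted p = 0.0620) and mitochondrial ribosomal proteins (-0.45, then -0.28, camera adjusted p = 0.252). They had camera adjusted p of 0.526 or 0.604 with an estimated correlation. Rpl7 of the large ribosomal subunit stood at -3.90 (-2.70 with the batch) and the cytochrome oxidase subunit Cox6b1 at -2.12 (-2.13 with the batch). Ketogenesis (-0.20), PPARα targets (-0.19), peroxisomal genes (-0.55) and lipogenesis (-0.20) were not called. Of the 16 genes fixed by name 0 passed, with values from -1.88 (Srebf1, the lipogenic transcription factor) to 2.17 (Mknk1), Fasn at -1.78 and the gluconeogenic Pck1 at -0.95. Mknk1 was high in keto 1 alone, with 406 and 24 counts in keto 1 and 2 heavy and 31, 56 and 96 in chow.

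The chow animals differed among themselves in these lipid genes. Cyp4a14 was at 24.8 CPM in the heavy library of chow 1, 1453 in chow 2 and 721 in chow 3, against 248 and 244 in keto 1 and 2. Fasn ran the other way, at 255, 61.3 and 45.5 CPM in chow and 24.9 and 45.2 in keto.

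**Figure D3:**
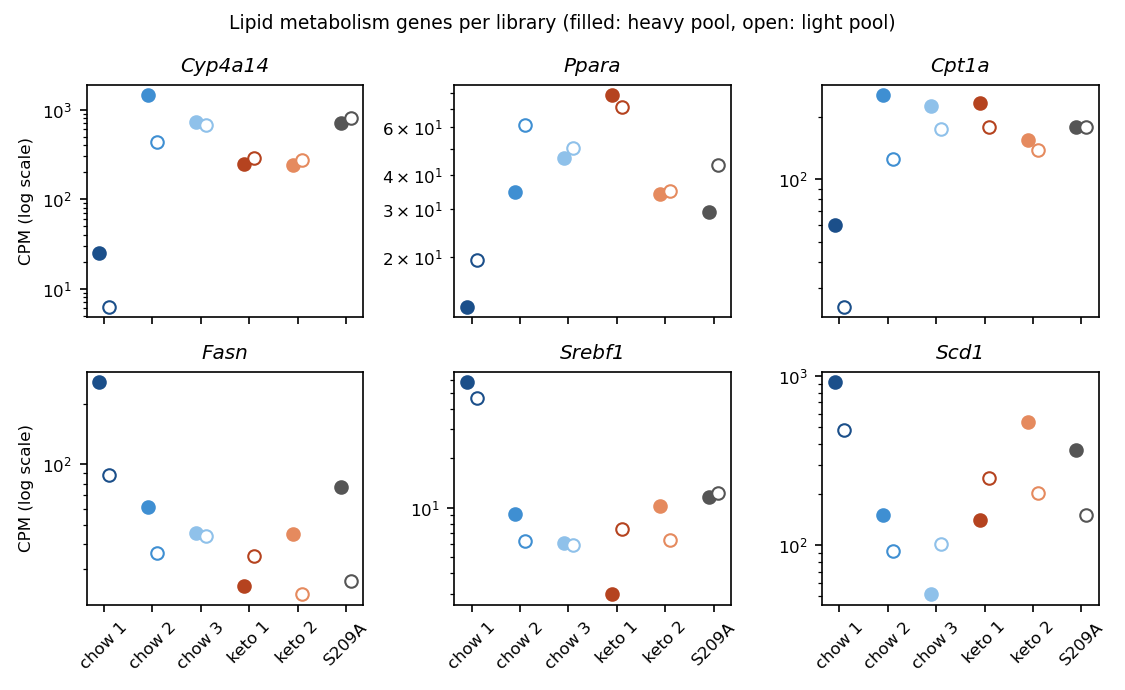
CPM on a log axis of 6 lipid metabolism genes in the heavy (filled) and light (open) library of each animal. For Cyp4a14 the heavy libraries of keto 1 and 2 (248 and 244) lay between chow 1 (24.8) and the other chow animals (721 and 1453).

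In the light pool, hemoglobin and mitochondrial RNAs lay higher in the ketogenic diet animals, and cholesterol synthesis mRNAs lay lower. The erythroid list was positive in 5 of 5 genes (median 2.61, camera adjusted p = 1.17e-06, 2.27 with the title batch), with 0 passing over all genes and 3 adjusted over the list alone. Its members Hba-a2 (3.18 ± 0.64), Hba-a1 (2.90) and Hbb-b1 (2.31), hemoglobin chains with near-identical copies, did not pass in edgeR (adjusted p = 0.796). Mitochondrially encoded RNAs were positive in 15 of 15 (median 1.15, 0.63 with the batch). Cholesterol synthesis was negative in 23 of 25 (median -0.75, -0.85 with the batch), with Fdps at -2.51 and the regulator Srebf2 at -1.62. Camera did not call it without chow 1 or without keto 2 (adjusted p of 0.114 and 0.498). In the mean of both pools cholesterol synthesis lay at -1.37 in chow 2, -0.97 in chow 3, -1.32 in keto 1 and -2.14 in keto 2 relative to chow 1. None of these lists held with an estimated correlation (camera adjusted p = 0.966 with an estimated correlation).

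edgeR called 0 of 10551 genes in the light pool, with 640 at an unadjusted p under 0.05 (246 higher, 394 lower), DESeq2 called 40 and limma-voom 0 (376 higher and 206 lower at an unadjusted p under 0.05, the opposite balance). The genes with the smallest p also held Tlcd4 (2.57), the deiodinase Dio1 (2.23), Perp (2.07), Neb (-2.59), Nav1 (-2.78) and Luc7l3 (-2.09), none of which passed (edgeR adjusted p = 0.796). U2af1, a splicing factor, held 0 counts in both keto libraries and 27, 20 and 60 in chow, and Ccdc141 2 and 0 against 44, 68 and 93. Camera called 5 lists. Ribosomal proteins (-1.19) and amino acid catabolism (-0.73) were lower, but not with the title batch (-0.08 and -0.42, camera adjusted p of 0.934 and 0.0540), and both had an adjusted p = 0.966 with an estimated correlation. Rpl7 stood at -3.02 (-2.52 with the batch) and the urea cycle enzyme Ass1 at -1.83 (-0.83 with the batch). PPARα targets (0.13), ketogenesis (0.37), peroxisomal (-0.14) and immediate early genes (0.42) were not called over all animals. With the batch, which leaves chow 1 and 2 as the reference, camera called them at 0.56, 0.78, 0.35 and 0.88 (adjusted p of 0.00127 to 0.0425, and 0.966 over all animals with an estimated correlation). For the PPARα, ketogenesis and peroxisomal lists chow 1 was the low one, since chow 2 lay above it by 2.20, 1.48 and 2.09 in the mean of both pools, keto 1 by 1.75, 1.32 and 1.99 and keto 2 by 1.13, 1.21 and 1.65. Of the 16 genes fixed by name 0 passed in edgeR, with values from -1.73 (Mknk1) to 0.79 (Mknk2), and Fasn stood at -0.96.

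Heavy over light, the measure of translation efficiency in the series' title, differed between the diets for single genes of the major urinary proteins, pheromone carriers that the liver secretes, though not for their sum, and for Park7 and Kcnq1ot1. On the ketogenic diet all 20 tested Mup genes had a negative value relative to chow (median -2.67, highest -1.09), and edgeR called 13 of them. Mup15 (-3.41 ± 0.62, edgeR adjusted p = 2.04e-04) and Mup9 (-3.23 ± 0.61, edgeR adjusted p = 4.19e-04) led. Park7, a redox-sensing chaperone, was lower by -2.77 ± 0.65 and Kcnq1ot1 higher by 3.65 ± 0.87 (edgeR adjusted p of 0.0143 and 0.018). Secreted protein genes were negative in 36 of 36 (median -1.03, camera adjusted p = 2.42e-14, adjusted p = 0.667 with an estimated correlation).

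edgeR called 20 genes, 3 higher and 17 lower, and 0 at a mean of at least 50 counts or without the animal as a block (229 and 323 at an unadjusted p under 0.05). Without the title batch the others included Mup16 (-2.81), Mup11 (-2.77), Mup17 (-2.76), Mup19 (-2.71), Mup10 (-2.63), Mup18 (-2.62) and Mup22 (-2.45), with edgeR adjusted p of 0.00789 to 0.0221. The Mup copies share sequence, and summed into 1 value the family stood at -2.30 ± 0.75 (edgeR adjusted p = 0.503) over all animals and was lower by -3.32 ± 0.51 (edgeR adjusted p = 1.16e-07) with the title batch. Its log2 heavy over light was 1.83, 1.10 and -1.90 in chow 1, 2 and 3 and -1.07 and -2.63 in keto 1 and 2. In chow 3 the copies named here lay higher, from -0.72 (Mup15) to 0.90 (Mup18), so the sum rests there on other copies. The rule picked these named copies for lying lower in both keto animals than in every chow animal. Mapk3 was higher by 3.31 ± 0.74 (edgeR adjusted p = 0.0109), with a log2 heavy over light of 4.02 in keto 1 and -2.80 and -2.55 in chow 1 and 2. Keto 2, at -1.08, lay below chow 3 at 0.09. Ccdc141 was called higher, with 26 and 21 counts in keto heavy and 2 and 0 in keto light. Not passing were Hdac4 (3.73), Zfhx4 (2.83), Frmd4b (2.57) and Pcm1 (2.57), with edgeR adjusted p of 0.123 to 0.229.

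Camera called 12 lists for this difference, and 12 of 12 were called in the same direction with the title batch, which leaves chow 3 out of the reference. In chow 3 the histone median was -0.21, against 0 and -0.02 in keto 1 and 2, that of β-oxidation 0 against -0.08 and 0, and that of nuclear RNA -0.12 against 0.32 and -0.24. Besides the secreted proteins these were peroxisomal genes (-0.64, 2 adjusted over the list alone), β-oxidation (-0.62), ketogenesis (-0.73), respiratory chain subunits (-0.41), ER chaperones (-0.61), pericentral (-0.71, 1 adjusted over the list alone), periportal (-0.51, 2) and amino acid genes (-0.32), histones (-1.32, 3) and erythroid markers (-1.42). Nuclear RNA was positive in 9 of 12 (median 1.51), with 1 passing over all genes and 5 adjusted over the list alone. All had a camera adjusted p = 0.667 with an estimated correlation. Members that did not pass were Fgb (-1.87), Apoh (-1.60), Ttr (-1.40), Ehhadh (-1.72), Acadl (-1.28), Hadha (-1.23), Pdia6 (-1.81), Cyp1a2 (-2.23), Cox6b1 (-2.41), Hba-a2 (-2.09) and Neat1 (1.62). The eIF4E pathway (0.27, 1 passing over all genes and 2 adjusted over the list alone) and the published phospho-eIF4E-sensitive mRNAs (0.43) were not called. Of the 16 genes fixed by name 0 passed, with Mknk1 highest at 2.90 (edgeR adjusted p = 0.0776) and Cyp4a14 lowest. The Mknk1 value rests on keto 1, with a log2 heavy over light of 3.78, while keto 2 at -1.10 lay below chow 3 at -0.27. With the title batch edgeR called 228 genes, which included all 20. Without chow 1, chow 2, keto 2 or chow 3 it called 3, 0, 2 and 211. Those called without keto 2 were 2 higher and 0 lower, so no Mup gene and not Park7 stayed called. Without keto 1 it called 20, of which 10 were among the 20 called over all animals.

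The S209A animal was compared with wild-type chow animals to ask how eIF4E phosphorylation bears on translation. Eif4e itself held 18 and 42 counts in its heavy and light library and 0 to 59 in the others. A change of 1 amino acid leaves the gene's counts in place, so this level does not check the label. With 1 animal the differences have no replicate check, and the edgeR counts below assume that it varies as the others do, which these data cannot check.

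With the pool labels as given, heavy over light in the S209A animal lay below each chow animal for Saa1, the inducible chaperone Hspa1b, Mup15 and Mup16. With the S209A pool labels exchanged, which is not excluded here, edgeR called 16 genes, of which 0 were among those called with the labels as given and in the same direction. Saa1 stood at -5.07 relative to chow (-5.27 against chow 3 with the title batch), with 243 counts in heavy and 882 in light. Its log2 heavy over light was -2.17 in S209A and 2.74, 2.48 and 2.94 in chow 1, 2 and 3, and with the labels exchanged Saa1 stood at -0.70. Mup15 stood at -6.10 (-4.52 with the batch), Mup16 at -4.73 (-4.33) and Hspa1b, with 6 and 152 counts, at -5.90 (-4.73). Wild-type keto 2 held 0 and 55 counts of Hspa1b, so a low ratio was not particular to S209A. Summed, the Mup family stood at -3.20 and at -0.85 with the batch, with a ratio of -2.75 in S209A and -1.90 in chow 3. The 5S rRNA copies n-R5s149 (4.51), n-R5s144 (4.50) and n-R5s146 (4.13) and Neb (3.15) stood on the higher side. Other copies were mixed: in S209A heavy and light n-R5s141 held 54 and 2 counts, n-R5s143 0 and 30 and n-R5s124 280 and 227. Under the assumption above edgeR called 29 genes, 7 higher and 22 lower, 14 with the title batch, of which 11 were among the 29, and 0 at a mean of at least 50 counts or without the animal as a block (279 and 356 at an unadjusted p under 0.05). It called 223 without chow 3, and 11 without chow 2.

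As a description of these libraries, and with the pool labels as given, list medians were placed among 10000 random lists. For heavy over light the acute phase list was at -1.88 (percentile 0, -1.45 with the batch, camera adjusted p = 0.456 with an estimated correlation), secreted proteins at -1.10 (0.08, -0.48), ER chaperones at -1.20 (0.22, -0.62), ribosomal proteins at -0.71 (0, -0.99), nuclear RNA at 2.00 (100, 0.48) and cholesterol synthesis at 0.55 (97.8, 0.86). With the pool labels exchanged these lists were at 0.37 (percentile 96.1), -0.29 (8.96), 0.09 (83.9), -0.45 (0.08), 0.43 (94.1) and -1.63 (0) in the same order. With the labels as given the eIF4E pathway was at 0.12 (71.7) and the published phospho-eIF4E-sensitive mRNAs at 0.23 (71.5). In the light library ribosomal proteins were at 1.60 (percentile 100) over all chow animals and 0.79 against chow 3, and nuclear RNA at -2.49 (0) and -0.71. In the heavy library cholesterol synthesis was at -0.90 (0) and -0.20, and the acute phase at -1.38 (0) and -0.11. With the pool labels exchanged, ribosomal proteins in light were at 1.51 (100) and nuclear RNA at -1.07 (0.07) over all chow animals. Cholesterol synthesis in heavy was then at -2.08 (0) and the acute phase at -0.14 (35.2).

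Within the pools edgeR called 0 genes in heavy (265 at an unadjusted p under 0.05, DESeq2 20, limma-voom 0, 166 without chow 3) and 0 in light (806, DESeq2 20, limma-voom 0, 286 without chow 3). In heavy the genes with the smallest p were Cyp2b10 (3.21), Rnf125 (3.01), the interferon-induced GTPase Gbp7, the glutathione transferase Gstm1 (2.37), the ferritin light chain Ftl1 (1.78), Erdr1 (-4.79) and n-R5s124 (-4.37), none of which passed. In light they were Gstp1 (2.56), Ino80b (2.53), Wfdc21 (2.48), Cyp1a2 (2.46) and Car3 (2.03), while Zdhhc7 and Cadps2 held 0 counts in S209A light and Kat6b, Drosha and n-R5s141 held 2. Of the 16 genes fixed by name 0 passed in edgeR in any S209A comparison, with values apart from Pdk4 from -2.22 in light to 2.83 in heavy over light, both in Mknk1. Pdk4, which restrains pyruvate oxidation, held 34 counts in S209A heavy and 2 in light, against 10 to 14 and 8 to 18 in chow. S209A lay beyond all 3 chow animals for 39.5% of genes in heavy, 58.1% in light and 55.1% in heavy over light, and with its pool labels exchanged for 43.1%, 47.2% and 44.8%, where chance gives 50%.

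**Figure D4:**
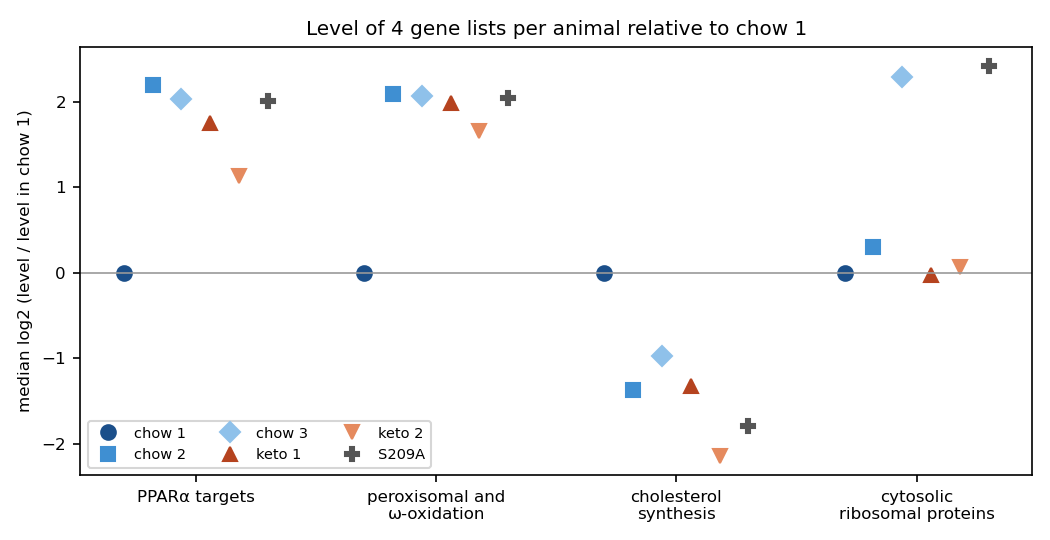
Median log2 level of 4 gene lists in each animal, as the mean of both pools relative to chow 1 (vertical axis), with 1 symbol per animal. PPARα targets lay at 2.20 and 2.03 in chow 2 and 3 and at 1.75 and 1.13 in keto 1 and 2, and ribosomal proteins at 2.29 in chow 3 and 2.41 in S209A.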

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

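All tests of explanations below were chosen after the results were seen.

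Heavy over light differed between diets in a test of the difference itself for 20 genes: it was higher in keto than in chow for Kcnq1ot1 (3.65) and Mapk3 (3.31, though keto 2 at -1.08 lay below chow 3 at 0.09), and lower for Mup15 (-3.41), Mup9 (-3.23), Mup16 (-2.81), Park7 (-2.77), Mup11 (-2.77), Mup17 (-2.76), Mup19 (-2.71), Mup10 (-2.63), Mup18 (-2.62) and Mup22 (-2.45), among others. The Mup copies share sequence, and their sum did not pass (-2.30, edgeR adjusted p = 0.503), with chow 3 at -1.90 between keto 1 and 2 at -1.07 and -2.63. The copies named here lay at -0.72 (Mup15) to 0.90 (Mup18) in chow 3, so the sum rests there on other copies. Between S209A and chow edgeR called 29 genes, on the assumption that this 1 animal varies as the others do, and 0 at a mean of at least 50 counts or without the animal as a block (279 and 356 at an unadjusted p under 0.05), with n-R5s149 (4.51), n-R5s144 (4.50), n-R5s146 (4.13) and Neb (3.15) on the higher side and Mup15 (-6.10), Hspa1b (-5.90), Saa1 (-5.07) and Mup16 (-4.73) on the lower side, with no replicate check and the pool labels as given.

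Chow 1 and chow 2 shared a contrast between the pools (r = 0.381 across 5122 genes, which are not independent replicates) that the other 4 animals did not share (r of -0.291 to -0.047 with chow 1 or 2). Exchanged pool labels in chow 3 or a keto animal would give a correlation with chow 1 or 2 near the negative of 0.381, and the lowest was -0.099. That holds only if the animal, rightly labelled, shared the contrast of chow 1 and 2, which is not known. Keto 1 and keto 2 correlated at only 0.077. The test therefore decides nothing, and the split of the chow libraries that exchanges the pools of chow 3 gave 50 calls against 24. Mitochondrial rRNA held 16.7% of heavy and 58.2% of light in chow 1, and 12.9% and 52.6% in chow 2. In keto 1 (47.3% and 37.6%) and keto 2 (74.2% and 51.8%) the order was the other way, so an exchange there stays open. For S209A an exchange stays open at -0.291 against chow 1. S209A correlated positively with chow 3, keto 1 and keto 2 (0.12, 0.101 and 0.238), which an exchange of S209A alone would turn. That counts against it only if those animals are rightly labelled, which is not known. The protein-coding shares of S209A (29.6% heavy, 38.0% light) ran as in chow 3 (29.7%, 39.2%). They ran opposite to chow 1 (15.9%, 6.53%) and chow 2 (22.2%, 8.16%), and an exchange in both S209A and chow 3 is not excluded by them. Too few mRNA counts are argued against for chow 3, S209A and keto 1, whose shallowest library held 0.635 M protein-coding counts against 0.583 M in chow 1 light, and stay open for keto 2 at 0.357 M. Processing that follows the headers stays open: with the header wording as a random block limma-voom called 36 genes for the diets and 19 without it, which decides nothing, since keto has a header wording of its own and the block correlation was negative (-0.408). The diet cannot account for chow 3, and it stays open, as does the genotype, for the other animals.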

How the results depend on the processing

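The ERCC scaling and the pseudocounts were not run. Of 1728 values of 130 named gene results under the alternatives, 1275 kept direction and side of the threshold, 196 lost the call, 250 gained one and 7 reversed, all with the S209A pool labels exchanged. Of 760 values of 56 called lists, 603 kept both, 152 lost the call and 5 reversed. The cause was not tested, except that leaving out animals or genes tests fewer of them. The keto comparisons rest on 2 animals, with 0.357 M protein-coding counts in keto 2 light, where 4816 protein-coding genes reached 10 counts (8924 in chow 3 heavy), and those of S209A on 1.

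Genes called between the pools in chow (24 in all animals) were 127 with DESeq2, 11 without a filter, 0 at a mean of at least 50 counts, 13 with protein-coding genes only, and 0 with no replicate block for the pairing of the pools. Without chow 1, chow 2, keto 1, keto 2 or chow 3 they were 5, 4, 8, 11 and 402. For keto in the heavy pool (0) they were 383 with DESeq2, 112 without a filter, 4 with limma-voom, 126 with the title batch, 2 with protein-coding genes only and 16 with the header wording as a random block, and from 0 to 108 without an animal (108 without chow 3). In the light pool (0) they were 40 with DESeq2 and 39 without a filter. For keto in heavy over light (20) they were 13 with DESeq2, 0 at 50 counts, 0 with no replicate block, 228 with the title batch and 36 with the header wording (19 in limma-voom without it, and a block correlation of -0.408, so that more calls are no support), and 3, 0, 2 and 211 without chow 1, chow 2, keto 2 and chow 3. The replicate numbers of chow and keto share only a number, and with them as a replicate block across diets 87, 5 and 198 genes were called in heavy, light and heavy over light. For S209A in heavy (0) they were 20 with DESeq2, 111 without a filter, 3 with the title batch and 0 to 166 without an animal (166 without chow 3). In light (0) they were 20, 101, 1 and 0 to 286 (286 without chow 3). In heavy over light (29) they were 0 at 50 counts, 15 with limma-voom, 0 with no replicate block, 14 with the title batch, 16 with protein-coding genes only, 16 with the S209A pool labels exchanged, and 11 without chow 2 to 223 without chow 3. With these labels exchanged n-R5s149 stood at -4.83, n-R5s144 at -3.92, n-R5s146 at -3.93, Neb at -2.89, Mup15 at 4.41, Hspa1b at 3.99 and Mup16 at 2.12.

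With an estimated correlation 0 lists were called in each of the 4 wild-type comparisons (22, 17, 5 and 12 with the preset). At a mean of at least 50 counts 9 were called in keto heavy. In keto light 9 were called with the replicate block across diets and 3 to 10 without an animal, and in keto heavy over light 7 to 17 without an animal. Medians that reversed were bile acid genes between the pools (-0.0386 at 50 counts, and -0.0864 without chow 1 to 0.683 without chow 3), PPARα targets between the pools (-0.0534 without chow 2 to 0.606 without chow 3), cholesterol synthesis in keto heavy (-1.10 without keto 1 to 0.0479 without chow 1) and oligopyrimidine translation factors in keto heavy (0.0602 with the replicate block across diets).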

Other observations

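All tests below were chosen after the results were seen.

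Chow 1 stood apart from every other animal in its lipid genes. As the mean of both pools, PPARα targets, which fasting and fat intake raise, lay above chow 1 by a median of log2 2.20 in chow 2 (21 of 22 genes), 2.03 in chow 3, 1.75 in keto 1, 1.13 in keto 2 and 2.01 in S209A. Peroxisomal and ω-oxidation genes lay above it by 2.09, 2.07, 1.99, 1.65 and 2.04 in the same order, and mitochondrial β-oxidation by 1.42, 1.73, 0.59, 0.66 and 1.83. Cholesterol synthesis lay below it by a median of -1.37, -0.97, -1.32, -2.14 and -1.80, and lipogenesis by -0.62, -0.65, -0.54, -1.02 and -0.63. Clock genes stood at 1.88, 2.08, 2.00, -0.20 and 0.84 relative to chow 1. In the light library Cyp4a14 was at 6.26 CPM in chow 1 and at 437 and 679 in chow 2 and 3, and Srebf1 at 46.5 CPM in chow 1 and at most 12.3 in any library of another animal.

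The processing named in the headers and titles, which chow 1 and chow 2 share, is argued against by the value of 2.20 between them. A lower depth or RNA yield in chow 1 stays open. The libraries were scaled by TMM, so neither need shift all liver mRNAs 1 way, and cholesterol synthesis at -1.37 does not decide it. Keto 2 held fewer protein-coding counts (0.55 M heavy and 0.357 M light, against 0.625 M and 0.583 M in chow 1), yet its PPARα targets lay above chow 1. An exchange of chow 1 with a keto animal stays open: 0 of the 2 such exchanges would put both keto animals above all chow animals in the PPARα list, which decides nothing, since chow 1 was the lowest. Chow 1 went with chow 2 in heavy over light (r = 0.381, against -0.097 and -0.099 with keto 1 and 2), in its header and in heavy mitochondrial rRNA (16.7%, against 12.9% in chow 2 and 47.3% and 74.2% in keto). Feeding state and time of day at collection were not tested, and no group of the design gives a biological explanation.

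Cytosolic ribosomal protein mRNAs were lower in keto than in chow over all animals, by a median of -1.71 in the heavy pool. With the title wording as a batch the median was -0.24, in line with a difference between the libraries titled fed and the others. The diet as the whole of the difference is argued against, since the higher keto animal lay at 0.067 relative to chow 1, while chow 3 lay at 2.29 and S209A at 2.41.

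For the 24 genes called between the pools in chow, the 6 libraries allow 10 splits, too few for a share under 0.05. The highest count among the other splits was 50, in the split that exchanges the pools of chow 3, and 2 of the 10 splits, the real one included, gave as many genes as the real one. Both were among the 4 splits that part all 3 pairs.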
